A study of Mus musculus with 6 samples.

How the data were processed

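RNA from Flk1-positive cells of day 4 embryoid bodies was measured on 6 Affymetrix mouse arrays, 3 biological replicates of Ldb1 wild-type and 3 of Ldb1 knockout embryonic stem (ES) cells. The deposited values were log2 expression levels per probe set. Per the labels, the authors' processing notes name RMA and the affy package, without versions. RMA as usually run corrects for background, sets the arrays to a common distribution and summarises the probes of each probe set. Each array held 45101 probe sets, of which 64 were controls. A probe set was used where its annotation gave exactly 1 gene, which held for 34945. The 932 probe sets with several genes and the 9160 with none were tested as probe sets and were not given a gene name. For each of 18193 genes the probe set with the highest mean over all 6 arrays was kept. Among these genes 9010 had more than 1 probe set, and 18032 had a chromosome in the GRCm38.p6 annotation.

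Wild-type and knockout arrays were compared with limma 3.58.1 in R 4.3.3, with jsonlite 2.0.0 for reading labels. Linear models were fitted per gene with lmFit and eBayes, and p-values were adjusted by Benjamini-Hochberg over genes, with a threshold of 0.05. A second fit took the replicate number as a block. To see whether the numbers paired the arrays, each array's deviations from its genotype's mean were correlated with those of the array of the same number. These correlations across probe sets were 0.698, 0.350 and 0.446 for numbers 1, 2 and 3. Each was above the limit of 0.1, and for every array the closest one of the other genotype had its own number. The labels do not say what the numbers stand for. The unblocked fit is reported first and the blocked value is given where it changes a call.

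A set of 23 gene lists for cell types and pathways was written from textbook knowledge. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists. The same test with the correlation estimated from the data was run as an alternative, as was fry, which tests whether the genes of a list move one way on balance. Of 824 listed members, 787 were measured. Chromosome medians were set beside 10000 random gene lists of the same size and matched mean level.

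The genes named were set by a rule. It took Ldb1 and Kdr, then the 10 largest positive and 10 largest negative differences past the threshold whose groups did not overlap. From each list it took up to 4 members past the threshold and up to 2 others with the highest mean. The rule was applied to each of the 2 fits, and members that no statement needed were left out. Nfe2, Runx1, Meis1, Bcl11a, Tal1, Gata2, Myl7, Sgce, Mcts2, Xist, Pou5f1, Nanog, Id1, Id2, Id4, Nodal, Bmp5, Kitl, Acta2, Tagln, Thy1, Dusp6, Pdgfa, Tubb1, Lcp1, Perp, Atf3, Zfp42, P4ha2, Cbfa2t3, Kdm5d, Cdx4, Mesp2, Rbp4, Krt18 and Sparc fell outside it and were chosen after their values were seen.

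The groups, tests, gene lists, naming rule and a first set of alternatives were chosen before the data were examined. That set held the replicate block, each array left out in turn, filters on dim probe sets, repeated quantile normalisation, subtracted array medians, trended robust variance, array weights, other choices of probe set, a fold limit of 2, a test against a fold of 1.5, and both other list tests. Alternatives that combined the block with another choice, left out a pair of arrays, took the number as a random block, or left out genes of chromosomes 8, 11, X and Y and imprinted genes were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

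The number of arrays limits the precision. The fits were tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale. The unblocked fit recovered 2% and 75% of them with 0 false calls. The blocked fit recovered 64% and 95%, with 8 false calls. The simulated arrays kept each gene's real mean per replicate number, with noise taken from the blocked fit. The advantage of the block was thus built in, and these rates hold only if the numbers pair the arrays.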

Results

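The series asks what the adaptor protein LDB1 does in the haemangioblast, a precursor of blood and endothelium. LDB1 binds LIM-domain proteins and, in blood cells, works in complexes with GATA1, TAL1 and LMO2. Flk1-positive cells, taken as the culture counterpart of the haemangioblast, were isolated from day 4 embryoid bodies. These were grown from Ldb1 wild-type and Ldb1 knockout mouse ES cells. Wild-type arrays also read cardiac mesoderm genes, such as Mesp1 (mean 11.60) and Hand2 (10.05), so the cells may be of several kinds. Their mix was not measured. Expression was measured on 6 arrays, 3 biological replicates per genotype, as log2 levels. Array medians lay between 5.71 and 5.77. The upper quartile was 7.92 in wild-type replicate 3 and between 8.14 and 8.27 in the other arrays. The replicate 3 arrays of both genotypes stood apart in their control probe sets. The 18S ribosomal RNA control read 11.9 in wild-type and 12.1 in knockout replicate 3, against 8.51 to 9.39 elsewhere. The 5′ control of Gapdh read 12.93 in both replicate 3 arrays, against 10.19 to 11.11 elsewhere. That of Actb read 12.97 in wild-type and 13.22 in knockout replicate 3, against 11.19 to 11.49 elsewhere. Their 3′ controls read 14.37 to 14.49 and 14.20 to 14.51 over all 6 arrays. The gap between 3′ and 5′ controls was thus wider in the arrays of numbers 1 and 2. Its cause was not tested, and these controls do not show replicate 3 to be the poorer pair.

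The first comparison asked whether the targeted gene and the marker used for isolation differed. Ldb1, on chromosome 19, was read by 1 probe set at 7.80 ± 0.50 (SD, n = 3) in wild-type and 7.37 ± 0.83 in knockout arrays. The difference of −0.43 (SE 0.45) was within the spread between replicates and did not pass the test (limma, adjusted p = 1.00), although the knockout array was lower in all 3 pairs. It was −0.05 without knockout replicate 2, −0.18 and −0.68 without wild-type replicate 3 or 2, and −0.88 without knockout replicate 3. The labels do not say which part of the gene was deleted, so a probe set outside that part leaves the genotype unchecked. Kdr, the gene of the VEGF receptor Flk1, stood at 12.12 ± 0.33 and 11.70 ± 0.44, a difference of −0.42 (limma, adjusted p = 1.00), and was also lower in the knockout array of all 3 pairs. That difference was −0.24 without knockout replicate 2, −0.26 without wild-type replicate 1 and −0.67 without knockout replicate 1.

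Knockout cells held far less of an embryonic globin transcript, of an imprinted transcript and of Y-linked transcripts. Hbb-bh1, an embryonic beta-like globin gene, fell 14.8-fold, from 8.84 ± 0.23 to 4.94 ± 0.39 (SD, n = 3; limma, adjusted p = 0.00494). Mest, expressed from the paternal allele, fell 24.2-fold, from 12.39 ± 0.52 to 7.79 ± 0.17 (adjusted p = 0.00494). Eif2s3y fell from 10.63 ± 0.35 to 3.17 ± 0.08 (adjusted p = 6.2e-05) and Uty from 6.95 ± 0.45 to 3.47 ± 0.04 (adjusted p = 0.00828). Each of these genes was lower in all 3 pairs. They were the 4 genes past the threshold among 18193, all lower in knockout cells, and 701 genes had an unadjusted p under 0.05, where chance gives 910. Of the probe sets without a single gene, 5 passed the threshold without the block and 6 with it, all lower. With 1 array left out, Eif2s3y stayed past the threshold and the others did not always. Adjusted p reached 0.0598 and 0.0716 for Hbb-bh1 without wild-type replicate 2 or knockout replicate 3, and 0.0500, 0.0575 and 0.0716 for Mest and 0.0833, 0.0688 and 0.103 for Uty without knockout replicate 1, 2 or 3. With a gene's probe sets averaged, Eif2s3y differed by −3.75 and Uty by −1.87, which did not pass (adjusted p = 0.111). Over all settings, chosen before or after seeing the data, Eif2s3y passed in 29 of 29 and Mest in 26 of 29. Hbb-bh1 passed in 28 of 31, with a limma adjusted p of at most 0.214, and Uty in 22 of 27.

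With the replicate number as a block, 62 genes changed, 42 lower and 20 higher in knockout cells, the 4 above among them. Hand2, a transcription factor gene of heart and limb, fell 6.51-fold (10.05 ± 0.65 to 7.35 ± 0.52; blocked adjusted p = 0.00103, unblocked 0.174). Plagl1, an imprinted zinc finger gene, fell 7.03-fold and Clic6 4.86-fold, and Nxf3 fell from 7.20 ± 0.78 to 4.36 ± 0.10, at the arrays' lower quartiles, with blocked adjusted p of 0.00559, 0.0194 and 0.0175 and unblocked 0.153, 0.756 and 0.148. The largest rise was that of Tcim, 4.86-fold from 7.11 ± 0.33 to 9.39 ± 0.27 (blocked adjusted p = 0.00199, unblocked 0.0542). The galectin genes Lgals3 and Lgals1 rose 3.68-fold and 2.64-fold, and the metallothionein genes Mt2 and Mt1, of metal binding, 2.71-fold and 2.53-fold. S100a6, Tgfbi, Gbp2, Pdgfrl and Cd9 rose between 2.61-fold and 3.27-fold. Blocked adjusted p for these 9 genes ran from 0.0111 to 0.0290 and unblocked from 0.148 to 1.00. Without probe sets that can bind several transcripts, the differences were −0.21 for Plagl1, −0.98 for Clic6 and −0.08 for Mt1, which turned its direction, and 1.00 for Tgfbi (blocked adjusted p = 0.130). With a gene's probe sets averaged, they were −1.16 for Hand2, whose other probe sets read near background, −1.02 for Plagl1 and 0.63 for Mt1. The blocked count was 267 without the arrays of number 2 and 815 without those of number 3.

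**Figure D1:**
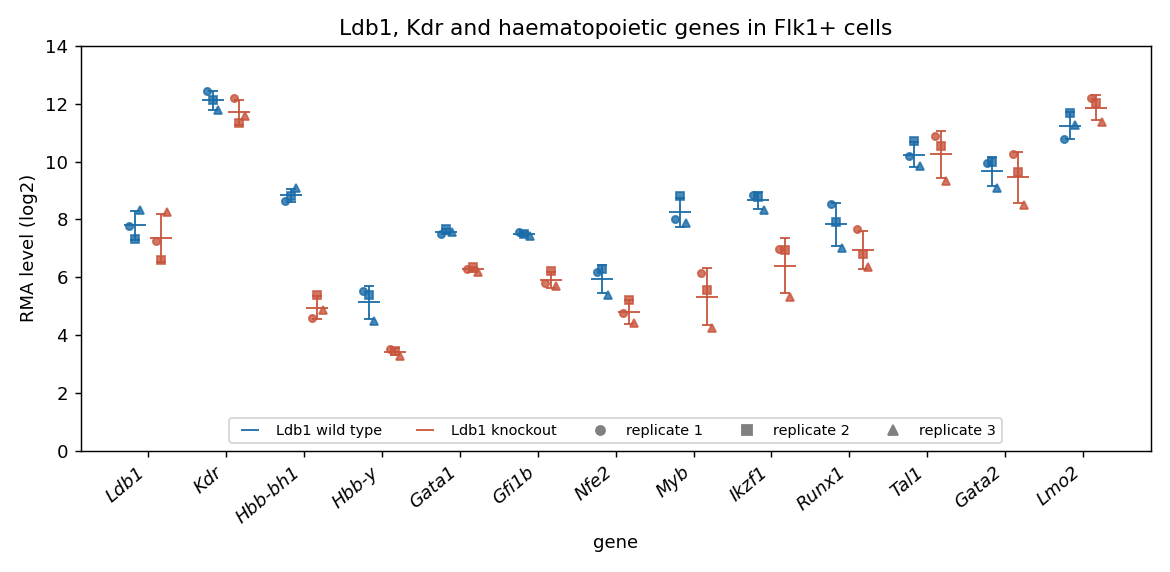
Log2 expression level of 13 genes in each array, with points for the 3 wild-type and 3 knockout arrays and bars for mean ± SD. Hbb-bh1, Gata1 and Gfi1b separate the genotypes, while Tal1 and Gata2 overlap.

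Haematopoietic transcription factor genes lay lower in knockout cells. Of 30 haematopoietic transcription factors 23 were lower, with a median difference of −0.33 (camera, adjusted p = 2.7e-07; adjusted p = 0.487 with an estimated correlation). The list did not pass fry (adjusted p = 0.240, blocked 0.110). With the block 5 of its members fell and 0 rose in limma. Myb, needed for definitive blood progenitors, fell 7.55-fold from 8.24 ± 0.50 to 5.33 ± 0.97, and Ikzf1, a lymphoid regulator, 4.78-fold from 8.66 ± 0.29 to 6.40 ± 0.95 (SD, n = 3). The erythroid and megakaryocytic regulators Gfi1b, Gata1 and Nfe2 fell 3.00-fold, 2.48-fold and 2.22-fold. Blocked adjusted p was 0.0238 for Myb and Ikzf1, 0.0194 for Gfi1b and Gata1 and 0.0334 for Nfe2. Without the block 0 members passed in limma, with adjusted p between 0.0542 for Gata1 and 0.756 for Nfe2 among these 5, and 8 members had an unadjusted p under 0.05. With a gene's probe sets averaged, the Ikzf1 difference was −1.19 (blocked adjusted p = 0.0527) and the Myb difference −1.80. The counts adjusted over the list alone were 8 lower and 0 higher without the block, and 13 lower and 1 higher with it. The members added by the block included Runx1, a master regulator of blood emergence, at −0.88, and Bcl11a, the higher one, at 0.83. Meis1, at −1.49, was lower in both counts. Their blocked adjusted p over all genes was 0.0893, 0.287 and 0.0910. The list's median was −0.10, −0.33 and −0.58 in pairs 1, 2 and 3. Both arrays of pair 3 stood apart in their control probe sets, and its wild-type array alone also in its quartiles (4.37 and 7.92).

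Other members of the LDB1 complex did not pass the test. Tal1 stood at 10.24 ± 0.43 in wild-type and 10.25 ± 0.81 in knockout arrays (SD, n = 3), Gata2 at 9.66 ± 0.51 and 9.46 ± 0.88, and Lmo2 at 11.24 ± 0.46 and 11.87 ± 0.43, with adjusted p of 1.00 for each. Lmo2 was higher in the knockout array of all 3 pairs, by 1.42, 0.34 and 0.10. The 29 LDB1 complex partners had a median of 0.01 and a mean of −0.04, with the test pointing lower (camera, adjusted p = 0.823). Gata1 was the 1 member called with the block. When adjusted over the list alone, 1 was lower without the block and 2 with it, the second being Cbfa2t3.

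Among 35 primitive erythroid genes 23 were lower, with a median of −0.06 and a mean of −0.33 (camera, adjusted p = 0.000384; adjusted p = 0.487 with an estimated correlation). With the block and without probe sets below the median level the call was lost (camera, adjusted p = 0.0748). The list passed fry without the block (adjusted p = 0.0403) but not with it (adjusted p = 0.0951). Hbb-bh1 fell without the block, and Gfi1b, Gata1, Nfe2 and Hbb-y joined it with the block. Hbb-y, another embryonic globin gene, went from 5.13 ± 0.57 to 3.42 ± 0.12 (blocked adjusted p = 0.0251, unblocked 0.274), a difference that was −0.23 without probe sets that can bind several transcripts. Adjusted over the list alone, 7 members were lower and 0 higher without the block, and 7 lower and 1 higher, Car2 at 0.64, with it. Gata1, Gfi1b and Nfe2 also belong to the transcription factor list. The erythroid medians by pair were −0.01, −0.02 and −0.22, so that most of the median lay in pair 3. The arrays of that pair were alike in their control probe sets but not in their distributions. The lower quartile was 4.37 in wild-type replicate 3 and between 4.22 and 4.28 in the other arrays. The 19 megakaryocyte and platelet genes had a median of −0.07 (adjusted p = 0.132). Itga2b, which encodes the early blood marker CD41, differed by −0.90 and was the 1 member lower when adjusted over the list alone, with Tubb1, at 0.53, the 1 higher with the block. The 35 myeloid and leukocyte genes had a median of −0.12 (adjusted p = 0.128; 0.0208 without wild-type replicate 1), with 0 members called by limma over all genes and 0 at an unadjusted p under 0.05, or 3 with the block. Lcp1, at 0.98, was its 1 member higher adjusted over the list alone with the block. In pair 3 the megakaryocyte and myeloid medians were −0.36 and −0.33, and in pairs 1 and 2 between −0.03 and 0.03. The stem cell factor receptor gene Kit stood at 7.70 ± 0.56 and 7.86 ± 0.99.

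Endothelial genes did not pass the test. Their median over 47 members was 0.01 (camera, adjusted p = 0.823). In limma 0 members were called in either count and 0 had an unadjusted p under 0.05, or 7 with the block. Aplnr, the apelin receptor gene, stood at 12.56 ± 0.24 and 12.17 ± 0.24 (SD, n = 3; adjusted p = 1.00) and was lower in all 3 pairs, by a mean of −0.40, or −0.26 without wild-type replicate 1. By pair the list's medians were 0.31, 0.12 and −0.38, so the replicate 3 arrays went the other way. Without knockout replicate 3 the median was 0.16 (adjusted p = 0.000119), and without the arrays of number 1 it was −0.13 with the block (adjusted p = 0.0186).

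**Figure D2:**
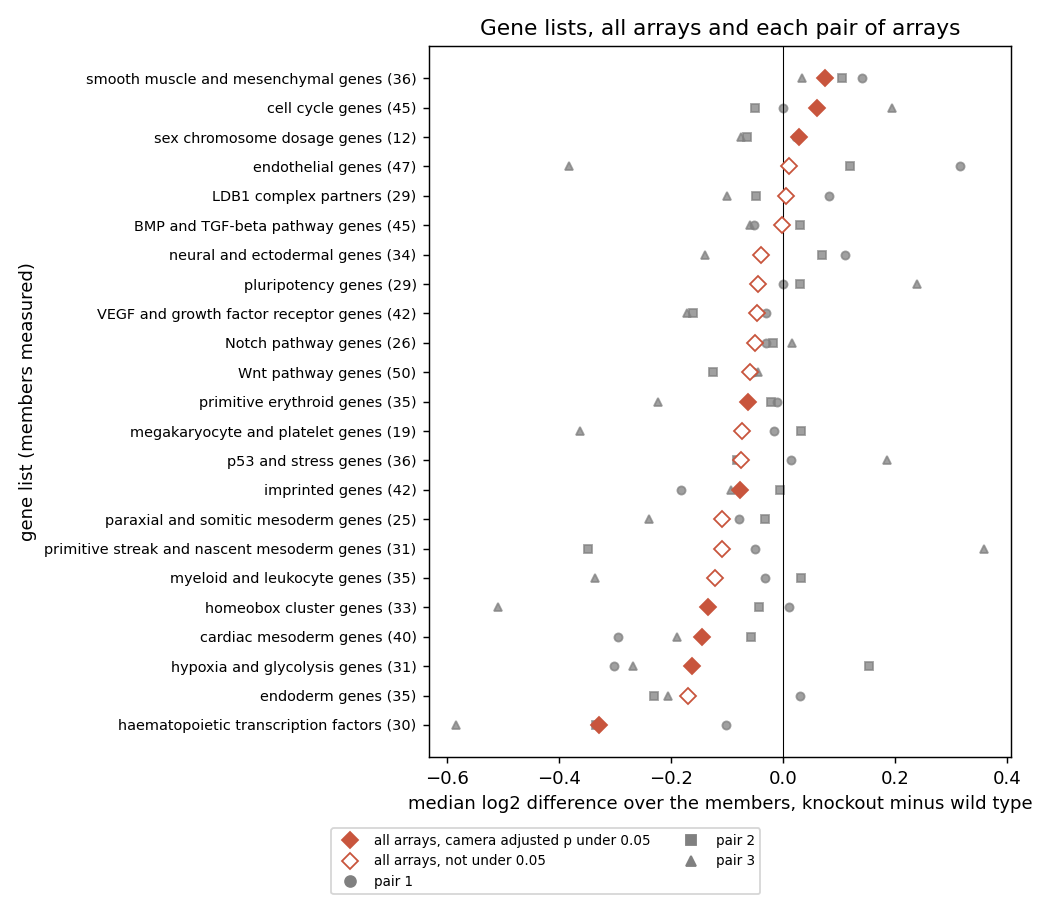
Median log2 difference, knockout minus wild-type, of 23 gene lists over all arrays and in each of the 3 pairs. Filled symbols mark lists with a camera adjusted p under 0.05, and the haematopoietic transcription factors lie lowest at −0.33.

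Cardiac mesoderm and homeobox genes were also lower. Of 40 cardiac mesoderm genes 28 were lower, with a median of −0.15 (camera, adjusted p = 0.000384; adjusted p = 0.487 with an estimated correlation). Hand2 was the 1 member called with the block, and adjusted over the list alone 3 members were lower without the block and 5 with it. Myl7, an atrial myosin light chain gene, was among these at −1.44, while Bmp4 (−0.29) and Mesp1 (−0.55) did not pass. Of 33 homeobox cluster genes 28 were lower, with a median of −0.13 (camera, adjusted p = 1.3e-06; adjusted p = 0.487 with an estimated correlation). Hoxb6, Hoxb2 and Hoxd1 fell 2.60-fold, 2.42-fold and 2.36-fold with the block (adjusted p = 0.0319, 0.0221 and 0.0238; unblocked 0.148, 0.148 and 0.153). With p adjusted over the list alone, 6 members were lower without the block and 7 with it. The 9 Hoxb members, on chromosome 11, were all lower, with a median of −0.72, and the 8 Hoxd members, on chromosome 2, had a median of −0.26. The 9 Hoxa members, on chromosome 6, and the 7 Hoxc members, on chromosome 15, had medians of −0.09 and −0.10 with 0 called by limma with the block. The list's medians by pair were 0.01, −0.04 and −0.51. Without both replicate 3 arrays the median was 0.03, and 1 of the 2 fits lost the call (camera, adjusted p = 0.159). At the preset correlation the list passed in 29 of 30 settings, the other fit without these arrays among them.

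The 25 paraxial and somitic mesoderm genes had a median of −0.11, and passed with the block (camera, adjusted p = 0.0239; adjusted p = 0.550 with an estimated correlation) but not without it (adjusted p = 0.0622). Left out singly, wild-type replicate 2 and knockout replicate 1 gave 0.00428 and 0.0294. In limma 0 members were called in either count and 0 had an unadjusted p under 0.05, or 2 with the block. The 31 primitive streak and nascent mesoderm genes had a median of −0.11 (adjusted p = 0.254), which passed without knockout replicate 3 (adjusted p = 0.0169). Fgf3, a growth factor gene, fell 2.61-fold with the block, from 10.42 ± 0.14 to 9.03 ± 0.33 (blocked adjusted p = 0.0256, unblocked 0.167). It was the 1 member lower adjusted over the list alone without the block; with it 3 were lower, Cdx4 and Mesp2 besides, and Nodal higher. The list's medians by pair were −0.05, −0.35 and 0.36.

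Smooth muscle and mesenchymal genes and cell cycle genes were slightly higher, and hypoxia and glycolysis genes lower. Over 36 smooth muscle and mesenchymal genes the median was 0.08 (camera, adjusted p = 0.0439; adjusted p = 0.672 with an estimated correlation). Over 45 cell cycle genes it was 0.06 (adjusted p = 0.0387; adjusted p = 0.487 with an estimated correlation), with pair 3 at 0.19 and the other pairs at or below 0. In pair 3, genes above the median level were higher on most chromosomes. Their median was 0.0839 on chromosome 15, 0.179 on chromosome 13 and between these on most others. The cell cycle value in pair 3 thus lay little above that of such genes in general, and does not set cell cycle genes apart. The 31 hypoxia and glycolysis genes had a median of −0.16 (adjusted p = 0.0143; adjusted p = 0.744 with an estimated correlation), with −0.30, 0.15 and −0.27 by pair, so that pair 2 went the other way. In these lists limma called 0 members over all genes, with 4 smooth muscle, 1 cell cycle and 2 hypoxia genes at an unadjusted p under 0.05. Adjusted over the list alone 3 smooth muscle genes were higher and 1 hypoxia gene, P4ha2 at −0.89, lower with the block. The smooth muscle call was lost without wild-type replicate 2 (0.173), wild-type replicate 3 (0.0756) or knockout replicate 1 (0.363), the first and last of which turned the median to −0.03 and −0.06. The cell cycle call was lost without wild-type replicate 2 (0.0525), wild-type replicate 3 (0.171) or knockout replicate 3 (0.592), and the hypoxia call without wild-type replicate 1 (0.417), knockout replicate 1 (0.0561) or knockout replicate 3 (0.301). With array weights the hypoxia test turned its direction (adjusted p = 0.928).

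Genes of chromosome 8 lay higher and those of chromosome 11 lower in knockout cells. Over 932 genes of chromosome 8 the median difference was 0.15 and 71.0% were higher in knockout cells. Without knockout replicate 1 that median was 0.0898, and with array weights 0.0793. Over 1443 genes of chromosome 11 it was −0.17 and 19.6% were higher. Of 10000 random lists 0 reached either median. The lists drew genes as if independent from the same 6 arrays, so this does not measure the spread between replicates. Among genes above the median level of all probe sets the medians were 0.26 and −0.23, and the other chromosomes apart from Y lay between −0.02 and 0.03. Of the 62 genes called with the block, 7 lie on chromosome 8, where 6 were higher, and 7 on chromosome 11, where 6 were lower. Tcim, Pdgfrl, Mt1 and Mt2 are on chromosome 8, as is Hand2, which fell. Ikzf1, Hoxb2 and Hoxb6 are on chromosome 11.

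**Figure D3:**
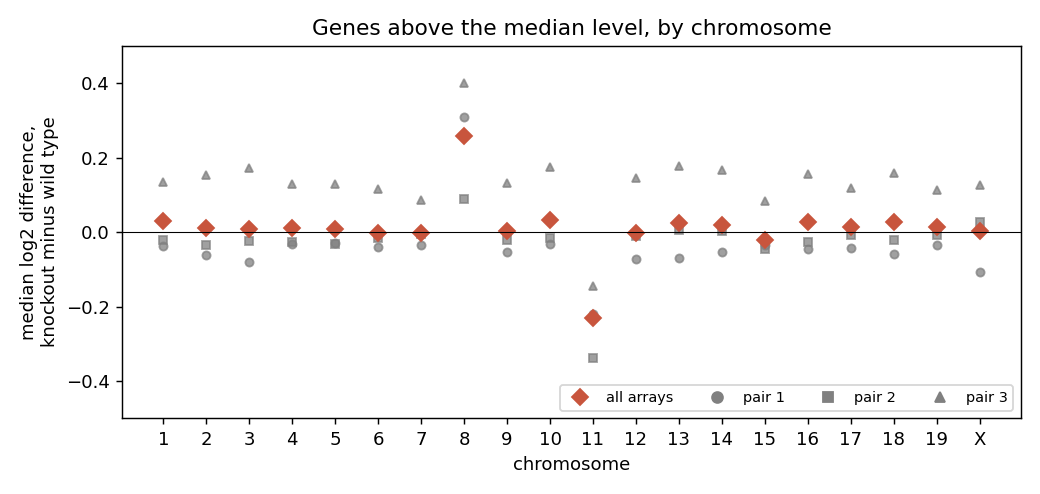
Median log2 difference, knockout minus wild-type, of the genes of each chromosome except Y, for genes above the median level, over all arrays and in each of the 3 pairs. Chromosome 8 lies at 0.26 and chromosome 11 at −0.23.

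Sex-linked and imprinted genes differed between the genotypes in a few members. Of 12 sex chromosome dosage genes, Eif2s3y and Uty fell, with the list's median at 0.03, its mean at −1.02 and the test pointing lower (camera, adjusted p = 0.0216; adjusted p = 0.487 with an estimated correlation). The blocked value was 0.0629, and without knockout replicate 1 it was 0.139. The count adjusted over the list alone was 2 lower without the block and 3 with it, the third being the Y-linked Kdm5d, which read 5.53, 6.56 and 3.45 in wild-type arrays, the last near the knockout mean of 3.32. Xist, which silences 1 of the X chromosomes in female cells, stood at 6.19 ± 0.35 and 6.27 ± 0.13 (SD, n = 3). Over 42 imprinted genes the median was −0.08 (adjusted p = 0.0439, blocked 0.0625; adjusted p = 0.542 with an estimated correlation). Without wild-type replicate 1 or 2, or knockout replicate 1 or 3, the unblocked value was 0.114, 0.105, 0.139 and 0.114. With the block 5 imprinted genes fell, Mest, Plagl1, Nnat, Mcts2 and Sgce, the last 3 by 4.01-fold, 2.39-fold and 2.24-fold (blocked adjusted p = 0.00592, 0.0238 and 0.0387; unblocked 0.130, 0.404 and 0.274). H13 rose 2.53-fold (blocked adjusted p = 0.0238, unblocked 0.333), but averaged over its probe sets, which went both ways, the difference was 0.19. Adjusted over the list alone, 5 imprinted genes were lower and 1 higher without the block, and 10 lower and 3 higher with it.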

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

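The block combined with another choice, pairs of arrays left out, the random block and the genes left out by chromosome were chosen after seeing the data. Of the alternatives set beforehand, the block raised the count of 4 genes to 62, array weights to 68 and counting probe sets to 10, and with arrays left out singly it ran from 1 to 6; the others left it within 1.5 times. With the block it was 62 without probe sets below the lowest 25% in level, 55 without those below the median, 26 with quantile normalisation repeated, 65 with medians subtracted, 48 with probe sets averaged, 58 without probe sets ending in _x_at or _s_at, 264 with trended robust variance, 517 with array weights, 25 for probe sets and 60 with a 2-fold limit. Leaving out the arrays of number 1, 2 or 3 gave 50, 267 and 815 with the block and, for number 3, 2 without it. The random block gave 37. Without genes of chromosomes 8, 11, X and Y and imprinted genes 1 gene was called, and 21 with the block. The 9 lists past the threshold became 5 with array weights, 2 with fry and 0 with an estimated correlation, and with the block 0 with either of the last. The 2 lists past fry were the sex chromosome dosage and primitive erythroid genes (fry, adjusted p = 0.0117 and 0.0403). Haematopoietic transcription factors did not pass it (fry, adjusted p = 0.240, blocked 0.110). Ldb1 passed in 1 setting, the block without the arrays of number 3, at −0.62 (adjusted p = 0.0181). Chromosome 8 and 11 medians were 0.258 and −0.231 without probe sets below the median level; with arrays left out singly they ran from 0.0898 to 0.205 and from −0.185 to −0.127, and with array weights they were 0.0793 and −0.180. The X median of −0.02 ran from −0.0501 to 0.00983 with arrays left out singly and was 0.0117 without those of number 3, with or without the block. The test's direction reversed for the hypoxia and glycolysis list with array weights (camera adjusted p = 0.928, median −0.0387) and for the endothelial list with the block and without the arrays of number 1 (median −0.127, adjusted p = 0.0186). Apart from the settings with fewer genes or arrays, the cause was not tested. Ldb1 ran from −0.88 to −0.05 with arrays left out singly. Among named genes not called over all genes, the differences of Tal1, Gata2, Kit, Xist, Pou5f1 and Nanog turned direction, and those of Kdr, Aplnr, Bmp4, Runx1, Bcl11a, Lmo2, Mesp1, Mesp2, Nodal, Pdgfa, Tubb1, Lcp1, Cbfa2t3, Kdm5d, Krt18 and Sparc moved by over 1.5 times with at least 1 array left out. The blocked fit changed no call among the results reported beyond those given with a blocked value. Background limits the fold of dim genes: in knockout cells Eif2s3y, Uty, Kdm5d, Cdx4 and Hbb-y lay below the arrays' lower quartiles (4.22 to 4.37), and Nxf3 within them.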

Other observations

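The tests of exchanged labels, of both explanations for the imprinted genes, of the share of Flk1-positive cells, of the range of each chromosome among arrays and of the list without chromosomes 8 and 11 with an estimated correlation were chosen only after the result was seen.

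BMP and TGF-β pathway genes went both ways. Of 45 members 23 were lower, the mean was 0.05 and the list did not pass (camera, adjusted p = 0.548). Adjusted over the list alone, with the block, 2 members were lower and 4 higher; without it, 1 was lower and 1 higher. Bmp5, a BMP ligand gene, differed by −0.88. Id1, Id2 and Id4, which encode inhibitors of basic helix-loop-helix factors, differed by 0.69, 1.32 and 1.74, and Nodal by 1.17. Over all genes their blocked adjusted p ran from 0.0700 for Bmp5 to 0.262 for Id1. In the smooth muscle and mesenchymal list, Acta2, Tagln and Thy1 were the 3 members higher adjusted over the list alone with the block, at 0.76, 0.76 and 0.81. The 42 VEGF and growth factor receptor genes had a median of −0.05 (adjusted p = 0.188; 0.0334 and 0.0145 without wild-type replicate 3 or knockout replicate 1). Adjusted over the list alone 2 were lower without the block, and with it 6 were lower and 2 higher. The stem cell factor gene Kitl was among the lower at −0.91, and the higher were Dusp6, which encodes an ERK phosphatase, at 1.52 and Pdgfa at 0.55.

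Among 29 pluripotency genes the median was −0.04 and the mean 0.13, with the test pointing higher (camera, adjusted p = 0.188; 0.0272 and 0.0136 without wild-type replicate 1 or knockout replicate 2). Dppa5a, an ES cell marker gene, rose 2.29-fold with the block (blocked adjusted p = 0.0315, unblocked 0.148). It was the 1 member higher adjusted over the list alone without the block, and Zfp42, at 0.78, joined it with the block. Pou5f1 and Nanog, core pluripotency factor genes, read 10.82 and 9.26 in knockout replicate 3 and at most 9.65 and 8.10 in the other arrays. Over 35 endoderm genes the median was −0.17 (adjusted p = 0.198; 0.0151 without knockout replicate 1), and with the block Spink1 fell 2.49-fold and Krt19 rose 2.31-fold (adjusted p = 0.0238 for both, unblocked 0.667). The endoderm counts adjusted over the list alone were 3 lower and 3 higher with the block, with Rbp4 (−0.92) and Sparc (−0.61) lower and Krt8 (0.65) and Krt18 (0.68) higher besides. Wnt pathway genes had a median of −0.06 (adjusted p = 0.198; 0.0197 without knockout replicate 1), and p53 and stress genes a median of −0.08 and a mean of 0.07, with the test pointing higher (adjusted p = 0.198; 0.0309 without wild-type replicate 1). Perp, at 1.19, was the 1 stress gene higher adjusted over the list alone without the block, and Atf3, at 1.03, joined it with the block. Notch pathway genes (median −0.05, adjusted p = 0.640) and neural and ectodermal genes (median −0.04, mean 0.02, adjusted p = 0.649) did not pass.

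Y-linked transcripts were low in all 3 knockout arrays, and chromosomes 8 and 11 were shifted in opposite directions. With each chromosome divided into 4 parts in order of position, the part nearest to 0 had a median of 0.218 on chromosome 8 and −0.223 on chromosome 11; this was meant to test for a few strongly changed genes, but these cannot move a median over so many genes, so it excludes nothing. A second active X chromosome was argued against by a median of X genes that differed from that of autosomal genes by −0.00141, while the count of 0 arrays with the Eif2s3y level of the other genotype restates the pattern and says nothing about exchanged labels. A difference in copy number between the ES cell lines is a candidate explanation for chromosome 11, where the pair nearest to 0 had −0.145. On chromosome 8 the pair nearest to 0 had 0.0888. These values hold each pair's general shift and do not set the chromosomes apart. Relative to other autosomes, pair 1 read 0.0747 in the wild-type and −0.0618 in the knockout array on chromosome 11. Pair 2 read −0.0085 and 0.110 on chromosome 8. Copy number is a less clear candidate for chromosome 8 because its wild-type arrays differed among themselves. Relative to other autosomes, wild-type arrays ran from −0.21 to −0.01 on chromosome 8. That range of 0.204, against at most 0.128 on autosomes other than 8 and 11, is not what a fixed copy number predicts. The knockout arrays lay between 0.11 and 0.13 on chromosome 8, a range of 0.0183, so the spread was that of the wild-type arrays. Both shifts were smaller than the 0.585 that 3 copies against 2 would give in every cell if array levels followed copy number in full. The medians depended on level, with 0.15 and −0.17 over all genes and 0.26 and −0.23 among those above the median level. Their size thus excludes no copy number. DNA was not measured. Loss of the Y chromosome in the knockout line, lines of different sex, and an effect of Ldb1 on these chromosomes were not tested.

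Imprinted genes held more calls than other genes. With the block 6 of 42 (14.3%) were called, against 56 of 18151 others (0.309%, two-sided Fisher's exact p = 5.83e-09). As large a share was held by 2 of 12 sex chromosome dosage genes (16.7%), 5 of 30 haematopoietic transcription factors (16.7%) and 5 of 35 primitive erythroid genes (14.3%). The haematopoietic and erythroid lists share Gata1, Gfi1b and Nfe2. Homeobox cluster genes held 9.09% and the remaining lists at most 5.71%. Imprinted genes were thus not alone in such a share, though most lists held less. Parental imprints that differ between the ES cell lines may account for the imprinted calls. The 21 genes expressed from the paternal allele had a mean difference of −0.73 (SD 1.16) and the 15 expressed from the maternal allele 0.20 (SD 0.44, two-sided permutation p = 0.00137). The permutation exchanged genes as if independent, though all came from the same 6 arrays, so its p does not measure the spread between replicates. The means also depend on the probe sets. Plagl1 (−2.81) was at −0.21 without probe sets that can bind several transcripts, and H13 (1.34) at 0.19 with its probe sets averaged. H19, also on the list, was not among these genes. Probe sets assigned to several genes entered neither mean. Those called with the block, of 3 and 2 genes, differed by −3.99 and −3.77 (limma over probe sets, blocked adjusted p = 0.00149 and 0.0140). The difference between the means thus holds only for genes with a probe set of their own. An effect of Ldb1 on imprinted genes stays open as untested, since DNA methylation was not measured and the labels do not say how many lines stand behind each genotype.

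The median of the haematopoietic transcription factor list was below 0 in all 3 pairs, while 7 of its 30 members were higher over all arrays. The shifts of chromosomes 8 and 11 were argued against as the only source of the median, since the 21 members on other chromosomes had a median of −0.295 (camera, adjusted p = 2.7e-08; adjusted p = 0.419 with an estimated correlation), and the replicate 3 arrays were argued against as the only source by a median of −0.249 without them. Fewer Flk1-positive cells stay open, since Kdr (−0.42) and Aplnr (−0.40) were lower in all 3 pairs without passing the test, with Kdr at −0.24 without knockout replicate 2. On the other side, the haematopoietic minus endothelial median was −0.358, with −0.424, −0.460 and −0.219 by pair. The cells had also been isolated as Flk1-positive. A weaker blood programme in the absence of LDB1 is another open hypothesis, with camera adjusted p at the preset correlation from 1.1e-14 to 0.000119 over 30 settings. With an estimated correlation it was 0.487 and, with the block, 0.550. On simulated data that test found a list shifted by 0.5 without the block (adjusted p = 0.00244) and missed it with the block (0.0965). The simulated list held genes drawn at random with independent noise, while the haematopoietic list had an estimated correlation of 0.286, or 0.111 with the block. The simulation therefore does not show what the test could find for this list. Differences between the ES cell lines other than those of chromosomes 8 and 11, and a different pace of differentiation, were not tested.

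For the unblocked count of 4 genes, 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many, and the highest other gave 0. For the blocked count of 62, 1 of the 4 splits that part all 3 pairs, the real one, gave as many, and the highest of the others, each of which exchanges the genotypes within 1 pair, gave 0. In both cases the splits are too few for a share under 0.05.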
